A study of Homo sapiens with 12 samples.

How the data were processed

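The samples were 12 RNA sequencing libraries of H69 cholangiocytes in 4 groups of 3 (vehicle, TGFβ, Aramchol, TGFβ + Aramchol). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the 2S Plus DNA library kit from IDT. Per the submitters' processing notes, reads were aligned to GRCh38 with STAR 2.7.9a and assigned to genes with featureCounts of Subread. The deposited table holds counts, as whole numbers of reads per gene and library, and these counts were the only measurement used. The strand setting and the annotation release are not given in the sources used here, so overlapping and antisense genes and multigene families are uncertain. Reads carried no molecular identifiers, so counting error is the least error that a count can have. All 12 count columns were matched to the groups. Of 62703 gene IDs 62625 had a symbol, and 1741 IDs share a symbol with another. Coordinates are those in the table.

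Total counts per library were 62114944, 58360888 and 63731156 for vehicle, 63821054, 68053666 and 59187804 for TGFβ, 52279922, 69421963 and 63768405 for Aramchol, and 67718299, 61867133 and 70339925 for TGFβ + Aramchol. Mitochondrially encoded genes took 7.81 to 9.45% of counts, ribosomal protein genes 3.55 to 4.07%, and MT-CO1, the gene with the most counts, 1.23 to 1.63%. No 2 libraries of the same group were duplicates of each other (pairs across groups were not checked). A count of 3 corresponds to 0.0427 to 0.0574 CPM, which was taken as the floor per library.

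Genes were filtered with filterByExpr, scaled by TMM (factors 0.930 to 1.09) and fitted with the quasi-likelihood negative binomial model of edgeR 4.0.16 under R 4.3.3, with 1 mean per group over all 12 libraries. The biological coefficient of variation was 8.90%. The 6 contrasts were TGFβ against vehicle, Aramchol against vehicle, TGFβ + Aramchol against TGFβ, against Aramchol and against vehicle, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Log2 CPM for principal components used a prior count of 2. The groups, contrasts, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

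Genes were named by rule: 20 genes fixed in advance in every comparison; the 6 largest rises and 6 largest falls among called protein coding genes with at least 5 CPM in the higher group and no overlap between groups; and the 3 members with the smallest p of each list that passed camera or had at least 3 called members. In all, 29 gene lists were fixed, with 662 genes measured. They cover TGFβ targets, matrix, epithelial and mesenchymal genes, secretory factors, senescence, fatty acid synthesis, cholesterol synthesis, LXR targets, PPARα and fatty acid oxidation, bile acid genes, ER stress and the integrated stress response, NRF2 targets, lipid peroxidation, cell cycle, interferon, glycolysis and hypoxia, YAP and TAZ targets, and Notch and Wnt targets. Others mark cholangiocytes, hepatocytes, fibroblasts, endothelial cells, leukocytes and keratinocytes, or RNA quality (mitochondrially encoded, immediate early, ribosomal protein and histone genes). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and beside it with the correlation estimated from the residuals and with fry. Calls within a list were also counted with p adjusted over the list alone.

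The opposition of Aramchol to TGFβ was measured as the number of TGFβ-called genes that were also called in the opposite direction in TGFβ + Aramchol against TGFβ, and as the orthogonal slope of TGFβ + Aramchol against Aramchol on TGFβ against vehicle, with a jackknife over libraries, first as 1 sample of 12 and then within groups. Shared libraries were allowed for by 20 simulations.

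The alternatives chosen then were RLE and upper quartile scaling, no filter, a stricter filter (at least 10 counts and a mean CPM of 1), DESeq2 1.42.0, a replicate block, only the 2 groups compared, each library left out in turn, an estimated correlation and fry. A term for the 4 libraries numbered 3, the libraries numbered 1 and 2 alone, a robust fit and the jackknife within groups were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

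The procedure was tested on simulated data with 50 genes changed at each fold, some raised and some lowered. In TGFβ + Aramchol against TGFβ, edgeR called 36% of genes at the smallest fold simulated and 80, 94 and 100% of genes changed 1.5-, 2- and 4-fold, with 10 false calls. In the interaction it called 12% at the smallest fold and 70, 86 and 98% at the others, with 4 false calls. A slope set to 0.9 came out as 0.904. The 20616 genes without a count and those under the filter were left out of the tests, and no library was left out of the main results.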

Results

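RNA was sequenced from H69 cells, a line of normal human cholangiocytes (the epithelial cells that line bile ducts) immortalised with a viral large T antigen. Cells kept without serum for 6 h were treated overnight in serum-free medium with vehicle, with TGFβ at 10 ng/mL, with Aramchol at 30 µM, or with both. TGFβ is a cytokine that drives matrix production and the loss of epithelial features. Aramchol is a conjugate of cholic acid and arachidic acid that lowers the activity of stearoyl-CoA desaturase (SCD), the enzyme that puts a double bond into saturated fatty acids. The dose of Aramchol is given once for the series and was taken to hold for both Aramchol groups. Each of the 4 groups had 3 libraries, so that 12 libraries were compared. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Total counts per library ran from 52279922 (Aramchol replicate 1) to 70339925 (TGFβ + Aramchol replicate 3). Of 62703 genes in the table, 20616 had no count in any library and 21567 were tested. All levels below are in CPM (counts scaled by library size), as mean ± SD with n = 3 libraries per group, and all fold changes are log2 values from edgeR.

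The first principal component held 58.8% of the variance and separated the libraries with TGFβ (43.2 to 64.6) from those without (-58.2 to -51.9). The second component (7.15%) set TGFβ (16.5 to 20.9) apart from TGFβ + Aramchol (-23.1 to -19.0), and Vehicle replicates 1 and 2 (24.8 and 27.3) apart from Aramchol (-15.6 to -10.1). Vehicle replicate 3 lay at -5.32 on this component, nearer to the Aramchol libraries than to its own group. On the third component (6.68%) the library numbered 3 was the highest of its group in all 4 groups, at 17.0 to 35.1 against -20.4 to -5.50 for the libraries numbered 1 and 2. The library names end in a running number that covers the libraries numbered 1 first, then those numbered 2, then those numbered 3. What this order stands for, and what else the number 3 shares across groups, is not given in the sources used here. Counts that depend on these 4 libraries are therefore given a second time below, with a term for number 3 in the fit and from the 8 libraries numbered 1 and 2 alone, both chosen after seeing the data.

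**Figure D1:**
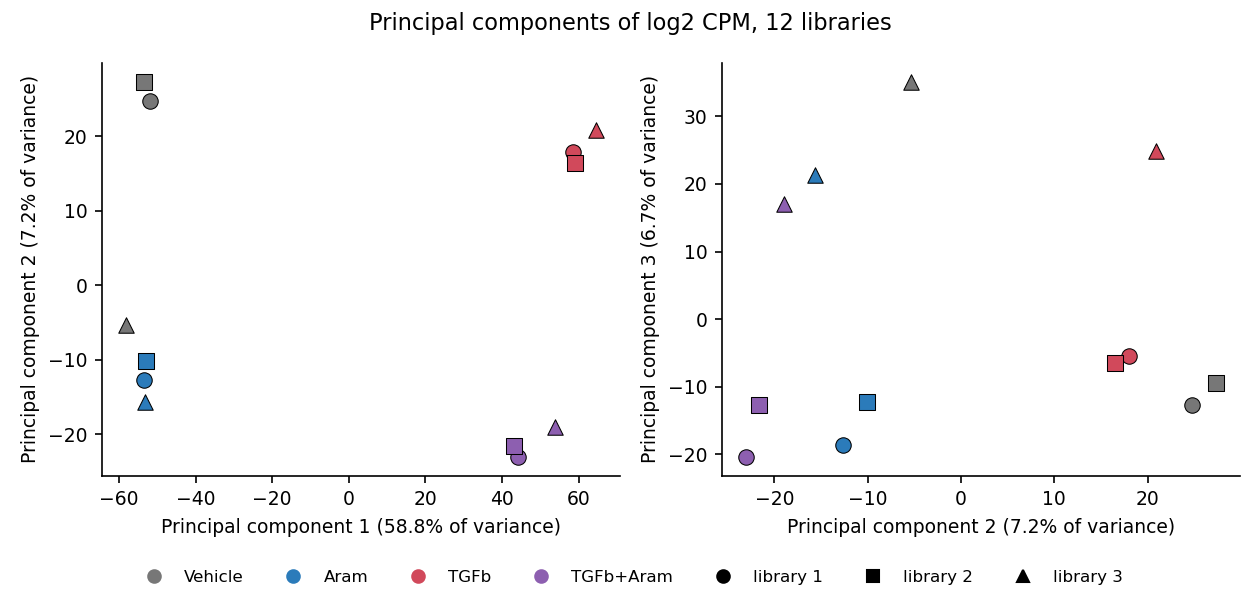
Principal components of log2 CPM for the 12 libraries, PC1 against PC2 and PC2 against PC3, with 1 point per library, coloured by group and shaped by library number. PC1 (58.8%) separates the libraries with TGFβ from those without, and on PC3 (6.68%) the libraries numbered 3 lie at 17.0 to 35.1, above the others.

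TGFβ against vehicle showed the response to the cytokine alone. FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436073, minus strand, GRCh38) encodes the matrix protein fibronectin. It rose 11.2-fold, from 659 ± 29.4 to 7418 ± 798 CPM. TGFBI (chromosome 5, 136028988 to 136063818), a secreted matrix protein, rose from 653 ± 68.2 to 6423 ± 349 CPM, and the inhibitory SMAD gene SMAD7 from 8.76 ± 1.49 to 88.4 ± 1.09 CPM. CDH1 (ENSG00000039068, chromosome 16, 68737292 to 68835537, plus strand), which encodes the junction protein E-cadherin, was 6.59-fold lower, at 11.1 ± 0.834 against 72.9 ± 9.67 CPM. The epithelial transcription factor gene ELF3 fell by 2.46 and the tight junction gene TJP3 by 3.02 on the log2 scale. All of these had an adjusted p under 0.05 by edgeR's quasi-likelihood test, with 4.07e-13 for FN1 and 1.39e-11 for CDH1 (edgeR, Benjamini-Hochberg). In all, 7978 genes (37.0%) passed, 4070 higher and 3908 lower (3601 and 4553 with upper quartile scaling, so that neither direction prevailed in both), and 2336 of them changed at least 2-fold, 1321 upward and 1015 downward. The 3 TGFβ and 3 vehicle libraries did not overlap for 46.6% of tested genes, where chance gives 10%.

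Of 34 measured direct targets of TGFβ signalling, 32 rose and 1 fell (33 and 1 adjusted over the list alone; camera adjusted p = 1.46e-27). BHLHE40, a transcriptional repressor, rose by 2.69 on the log2 scale. Of 52 matrix and fibrosis genes, 43 rose and 3 fell (43 and 3 adjusted over the list alone; camera adjusted p = 2.48e-24). COL4A1 (chromosome 13, 110148963 to 110307157), a chain of basement membrane collagen, went from 119.8 ± 3.73 to 796 ± 6.16 CPM. COL1A1 (chromosome 17, 50184101 to 50201632), a chain of fibrillar collagen, went from 1058 ± 92.9 to 4752 ± 782 CPM. The metalloproteinase gene ADAM19 rose 7.32-fold. On the mesenchymal side of epithelial-mesenchymal transition, 20 of 24 genes rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 1.23e-15). ITGA11, a collagen receptor subunit, went from 1.28 ± 0.540 to 93.7 ± 15.3 CPM. SNAI1, a repressor of E-cadherin, rose by 3.47 on the log2 scale and VIM, the intermediate filament vimentin, by 1.21. On the epithelial side, 4 of 27 genes rose and 13 fell (4 and 15 adjusted over the list alone; camera adjusted p = 0.00111). Of 15 fibroblast and myofibroblast markers, 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.000448). Among them were FAP, from 0.578 ± 0.305 to 13.5 ± 0.399 CPM, TAGLN, from 11.1 ± 3.93 to 137 ± 13.8 CPM, and PDGFRB, 4.29-fold higher. With an estimated correlation, the adjusted p was 0.0342 for the targets and for the mesenchymal genes, 0.0527 for the matrix genes, 0.420 for the epithelial genes and 0.263 for the fibroblast markers (camera in limma). With a term for number 3 as well, the targets (0.0881) and the mesenchymal genes (0.105) missed the threshold.

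**Figure D2:**
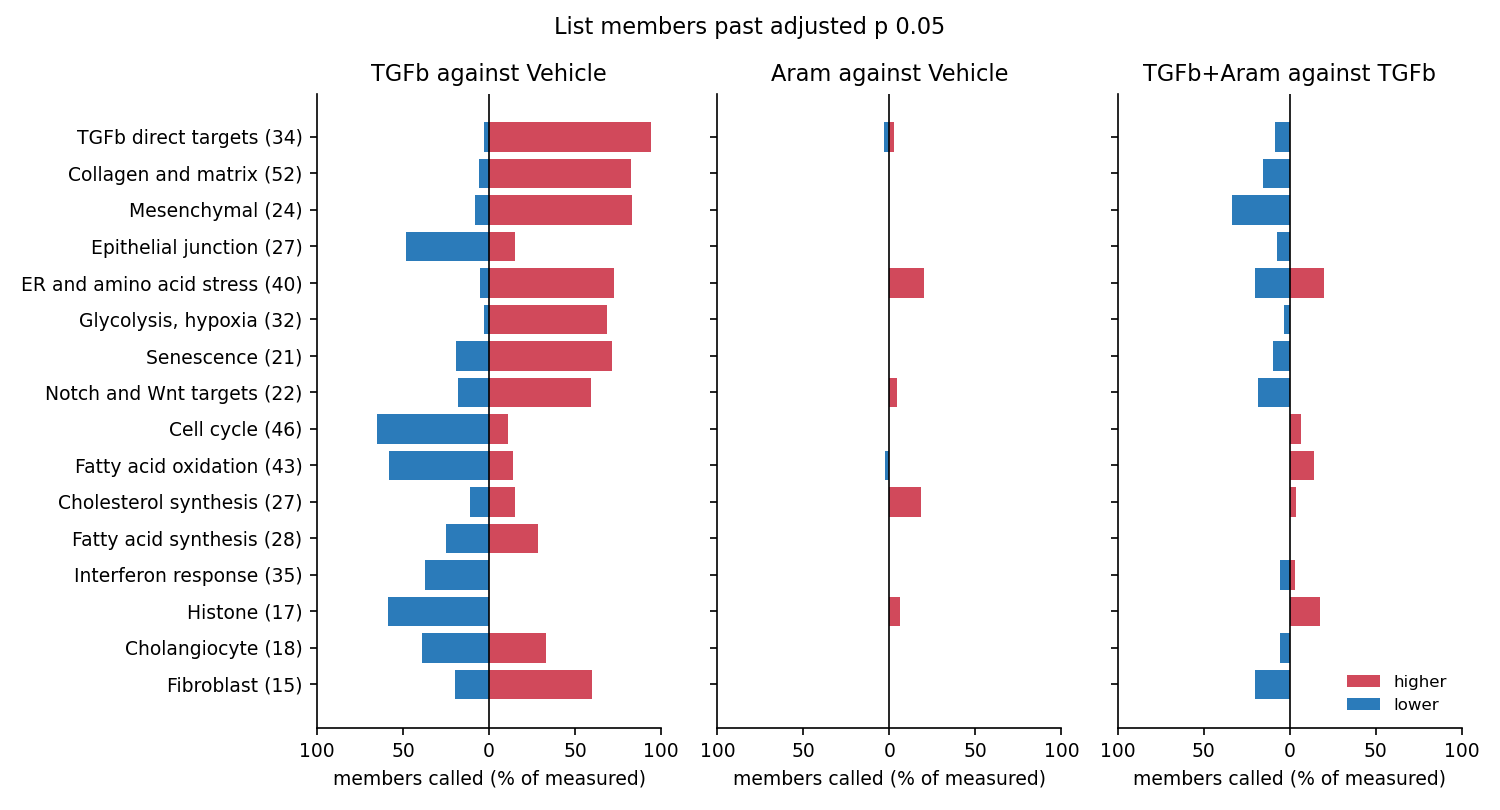
Percent of measured members of 16 gene lists called higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 (edgeR), for TGFβ against vehicle, Aramchol against vehicle, and TGFβ + Aramchol against TGFβ. TGFβ raised 43 and lowered 3 of 52 matrix genes, and with Aramchol added to TGFβ 8 of the 52 fell and 0 rose.

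Genes of growth arrest and metabolism moved as well. Of 21 senescence genes 15 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 1.48e-07). The cell cycle inhibitor gene CDKN2B was at 193 ± 1.07 against 44.6 ± 9.06 CPM and CDKN2A 1.76-fold higher. Of 46 cell cycle genes 5 rose and 30 fell (5 and 30 adjusted over the list alone; camera adjusted p = 5.36e-08). E2F2, a driver of S phase entry, was 3.54-fold lower. In the list of PPARα targets and fatty acid oxidation, 6 of 43 rose and 25 fell (6 and 27 adjusted over the list alone; camera adjusted p = 2.6e-05). PDK4 (chromosome 7, 95583499 to 95596516), a kinase that restrains glucose oxidation, fell from 11.4 ± 0.941 to 1.87 ± 0.0712 CPM. CPT1A (chromosome 11, 68754620 to 68844410), which carries fatty acids into mitochondria, fell from 60.4 ± 0.444 to 30.2 ± 3.50 CPM. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 3.41 on the log2 scale. Glycolysis and hypoxia genes rose in 22 of 32 cases and fell in 1 (23 and 1 adjusted over the list alone; camera adjusted p = 5.1e-12). The angiogenic factor gene VEGFA was 5.29-fold and the glycolytic regulator gene PFKFB3 3.37-fold higher. Of 40 genes of the endoplasmic reticulum (ER) stress and integrated stress response, 29 rose and 2 fell (30 and 2 adjusted over the list alone; camera adjusted p = 1.75e-10). The amino acid transporter gene SLC7A5 rose by 2.16 on the log2 scale. With an estimated correlation, the adjusted p (camera in limma) was 0.0943 for senescence, for PPARα and fatty acid oxidation and for glycolysis, 0.0527 for the cell cycle and 0.111 for the stress genes. SCD (ENSG00000099194, chromosome 10, 100347233 to 100364826, plus strand), the target of Aramchol, was 2.20-fold higher, at 1034 ± 14.7 against 469.9 ± 79.0 CPM (edgeR adjusted p = 3.38e-07). Of 28 SREBP1 and fatty acid synthesis genes, SCD included, 8 rose and 7 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.980). MLXIPL, a glucose-sensing transcription factor, fell by 3.46 on the log2 scale.

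Other lists gave mixed results with TGFβ. Notch and Wnt targets rose in 13 of 22 cases and fell in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 4.06e-05, and adjusted p = 0.0943 with an estimated correlation). The Wnt feedback gene NKD1 went from 0.294 ± 0.0308 to 23.9 ± 3.56 CPM. Of 18 immediate early genes 10 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.000543, and adjusted p = 0.111 with an estimated correlation). JUNB rose 5.01-fold. Of 23 YAP and TAZ targets 11 rose and 5 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.0302, and adjusted p = 0.691 with an estimated correlation). Keratinocyte genes rose in 9 of 14 cases and fell in 3 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00557, and adjusted p = 0.338 with an estimated correlation). KRT17 went from 42.1 ± 16.9 to 602 ± 41.7 CPM. Replication-dependent histone genes fell in 10 of 17 cases and rose in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.00189, and adjusted p = 0.0943 with an estimated correlation). They belong to multigene families whose reads may be split between copies, so single members are uncertain. Interferon genes fell in 13 of 35 cases and rose in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 0.00337, and adjusted p = 0.691 with an estimated correlation). In the libraries numbered 3, 24 of these 35 genes were lower and 0 higher than in the libraries numbered 1 and 2.

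The secretory list of cytokines and growth factors did not move one way. Of its 35 genes 11 rose and 14 fell (11 and 15 adjusted over the list alone; camera adjusted p = 0.756), and its median log2 fold change was -0.05 against a mean of 0.00. IL11, a cytokine tied to fibrosis, went from 5.90 ± 2.26 to 189.9 ± 2.34 CPM. PDGFB, a growth factor for mesenchymal cells, rose by 3.54 on the log2 scale, while the chemokine gene CXCL5 was 4.01-fold lower. IL6 was at 54.2 ± 20.9 and 67.2 ± 12.4 CPM (edgeR adjusted p = 0.492, and 0.0121 with a term for number 3), and the chemokine gene CCL2 had a log2 fold change of 0.29 (edgeR adjusted p = 0.451). In the libraries numbered 3, 18 of the 35 secretory genes were lower and 2 higher. Among 18 cholangiocyte markers 6 rose and 7 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.575). The water channel gene AQP1 was at 8.09 ± 0.572 against 0.385 ± 0.0160 CPM. The keratins of bile duct cells were close to the threshold, with KRT7 rising by 0.77 (edgeR adjusted p = 0.0218) and KRT19 falling by 0.57 (edgeR adjusted p = 0.0203) on the log2 scale. KRT7 missed the threshold without TGFβ replicate 1 or 2 (up to 0.0654). KRT19 missed it without TGFβ replicate 1 or 2 or Vehicle replicate 1 or 2 (up to 0.110). The fatty acid synthase gene FASN (0.40, edgeR adjusted p = 0.0307) missed it without TGFβ replicate 2 or 3 or Vehicle replicate 3 (up to 0.133). The other 95 of the 98 called genes named by rule kept their calls without each library in turn.

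Markers of other cell types and signs of RNA quality were read the same way. Of 11 hepatocyte markers 2 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.0667). HNF4A, a liver transcription factor, went from 0.330 ± 0.101 to 6.81 ± 2.35 CPM, while the fibrinogen gene FGG was 5.76-fold lower. Of 6 leukocyte markers 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.563). The receptor gene CSF1R rose by 5.02 on the log2 scale while CD14 fell by 2.52 on the log2 scale. Of 11 endothelial markers 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0996). The camera adjusted p was 0.0667 for mitochondrially encoded genes (2 of 13 higher, 0 adjusted over the list alone) and 0.0996 for ribosomal protein genes (1 of 37 higher, 0 adjusted over the list alone). Cholesterol synthesis genes (4 of 27 higher, 3 lower; 4 and 3 adjusted over the list alone; camera adjusted p = 0.987), LXR targets (4 of 14 higher, 4 lower; 4 and 4 adjusted over the list alone; 0.493), bile acid genes (3 of 8 higher, 2 lower; 3 and 2 adjusted over the list alone; 0.493), NRF2 targets (9 of 24 higher, 5 lower; 9 and 6 adjusted over the list alone; 0.445) and lipid peroxidation genes (4 of 14 higher, 4 lower; 4 and 4 adjusted over the list alone; 0.756) did not pass. The largest rises by rule were in genes with few or no counts in vehicle. CGB8, a chorionic gonadotropin gene with near-identical copies and therefore uncertain, was at 7.73 ± 1.29 CPM with TGFβ and at 0 in every vehicle library, where 3 counts correspond to at most 0.0514 CPM. KANK4 was at 27.6 ± 1.64 against 0.0604 ± 0.0267 CPM, COMP at 17.9 ± 5.16 against 0.0700 ± 0.0523, R3HDML at 9.68 ± 4.62 against 0.0259 ± 0.0448 and AMTN at 8.62 ± 2.89 against 0.0155 ± 0.00104. CHRNA9, at 0.0632 ± 0.0350 CPM in vehicle, also rose. The largest falls were in the mucin gene MUC6, from 147 ± 42.8 to 1.78 ± 0.213 CPM, and in STEAP4, INHBB, RCSD1, CHI3L1 and FGA, which were 30.1-, 23.6-, 19.7-, 17.9- and 16.4-fold lower.

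Aramchol against vehicle showed the response to the compound in unstimulated cells. SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand), which encodes the cystine importer, rose 2.94-fold, from 2.77 ± 0.272 to 8.16 ± 1.51 CPM. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956512, plus strand), which degrades glutathione, rose 2.65-fold, from 3.43 ± 0.636 to 9.10 ± 0.812 CPM. The other largest rises by rule were in the glycine transporter gene SLC6A9, by 0.81 on the log2 scale, the histone gene H2AC6 by 0.62, the amino acid transporter subunit gene SLC3A2 by 0.59 and the pseudokinase gene TRIB3 by 0.55. H2AC6 belongs to a multigene family and is uncertain. ATF4, the transcription factor of the integrated stress response, rose by 0.43. The largest falls were in ID3, an inhibitor of differentiation induced by BMP signalling, by 0.91 on the log2 scale, CHI3L1 by 0.79, GFRA1 by 0.69, SEMA6C by 0.56, GDAP1 by 0.41 and RAB4A by 0.41. The adjusted p was 0.00131 for SLC7A11, 0.000742 for CHAC1 and 0.00248 for ATF4 (edgeR's quasi-likelihood test, Benjamini-Hochberg). SCD was at 619 ± 77.0 against 469.9 ± 79.0 CPM (log2 fold change 0.40, SE 0.10, edgeR adjusted p = 0.139), and FN1 was at 659 in both groups (edgeR adjusted p = 0.997).

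In this comparison 77 genes passed the test, 51 higher and 26 lower, against 2533 at an unadjusted p under 0.05, and 6 changed at least 2-fold (5 higher, 1 lower). With upper quartile scaling 37 rose and 38 fell. The 2 groups did not overlap for 16.0% of genes, where chance gives 10%. The count changed when single libraries were left out, also libraries outside the 2 groups. It was 611 without Vehicle replicate 3 (222 higher and 389 lower). Without Aramchol replicates 1, 2 and 3 it was 18, 16 and 79, and without Vehicle replicates 2 and 1 it was 23 and 24. It was 33 and 45 without TGFβ replicates 2 and 1. It was 39 and 51 without TGFβ + Aramchol replicates 2 and 1, and 49 without TGFβ replicate 3. It was 5 with only the 2 groups compared, 538 with a term for number 3 (295 higher and 243 lower), 1544 from the libraries numbered 1 and 2 (704 higher and 840 lower) and 396 by DESeq2. Rises therefore did not prevail in every setting. Of the 16 called genes named by rule, 4 kept their calls without each library in turn, SLC7A11, CHAC1 and ATF4 among them. The other 12 missed the threshold without 1 or more libraries. SLC3A2 reached 0.111 without Aramchol replicate 1, H2AC6 missed it without each library but Vehicle replicate 3 (up to 0.209), TRIB3 0.0921 and CHI3L1 0.271 without Aramchol replicate 2, and ID3 and SLC6A9 0.117 and 0.150 without Vehicle replicate 2.

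Of 40 ER stress and integrated stress response genes 8 rose and 0 fell (17 and 3 adjusted over the list alone; camera adjusted p = 1.2e-08, and adjusted p = 0.686 with an estimated correlation). Of 27 cholesterol synthesis genes 5 rose and 0 fell (17 and 1 adjusted over the list alone; camera adjusted p = 3.84e-17, and adjusted p = 0.686 with an estimated correlation). Of these, 25 had a positive log2 fold change, with a median of 0.27. The sterol carrier gene STARD4 rose by 0.38 on the log2 scale. Of 28 SREBP1 and fatty acid synthesis genes 0 passed (7 higher and 0 lower adjusted over the list alone; camera adjusted p = 9.04e-05, and adjusted p = 0.686 with an estimated correlation). INSIG1 was at 195 ± 27.4 against 139 ± 18.4 CPM (edgeR adjusted p = 0.0966) and LPIN1 at 90.1 ± 10.2 against 71.3 ± 5.18 CPM (edgeR adjusted p = 0.124). With a term for number 3, SCD (0.0329), INSIG1 (0.0124) and LPIN1 (0.0169) passed. Much of their rise lay in the libraries numbered 3, since Vehicle replicate 3 was the lowest and Aramchol replicate 3 the highest of the 6 libraries for SCD (380.5 and 707 CPM), INSIG1 (118.5 and 226.5 CPM) and LPIN1 (65.5 and 101.8 CPM). From the libraries numbered 1 and 2 the log2 fold changes were 0.16, 0.26 and 0.18 (edgeR adjusted p = 0.00322 for INSIG1 and 0.0536 for LPIN1, with SCD just under 0.05), against 0.40, 0.49 and 0.34 from all. Of 35 interferon genes 0 passed (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.39e-05, and adjusted p = 0.901 with an estimated correlation). Vehicle replicate 3 and Aramchol replicate 3 are both among the 4 libraries in which 24 of them were lower. For the members named by rule, replicate 3 was lowered more in Aramchol. MX2 was at 126.5 CPM in Aramchol replicate 3, against 220.8 and 219.8 in replicates 1 and 2. In Vehicle replicate 3 it was at 116.6 CPM, against 134.7 and 125.1. IRF7 went the same way, and TAP1 was lower in Aramchol replicate 3 but not in Vehicle replicate 3. The camera test also passed for the secretory list, lower (0 of 35 called, 3 lower adjusted over the list alone; camera adjusted p = 0.00404), for mitochondrially encoded genes, lower (0 of 13 called, 2 lower adjusted over the list alone; 0.0169), for ribosomal protein genes, lower (0 of 37 called; 0.00551), and for cell cycle genes, higher (0 of 46 called; 0.0257). With an estimated correlation, their adjusted p (camera in limma) was 0.901, 0.901, 0.919 and 0.686. Neither the TGFβ targets (1 of 34 higher, 1 lower; camera adjusted p = 0.521) nor the matrix genes (0 of 52 called; 0.641) passed. The matrix list had a median of -0.01 and a mean of -0.05, while the direction of its camera test was upward. The mesenchymal list (0 of 24 called, 2 lower adjusted over the list alone; camera adjusted p = 0.860) had a median of 0.00 and a mean of -0.04, and the histone list (1 of 17 higher, 4 higher and 1 lower adjusted over the list alone; 0.0687) a median of 0.07 and a mean of -0.12.

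TGFβ + Aramchol against TGFβ, the comparison that the series title names, showed what Aramchol changed in stimulated cells. FN1 was 1.80-fold lower, at 4110.0 ± 434 against 7418 ± 798 CPM (edgeR adjusted p = 0.00025). TGFBI was at 4524 ± 484 against 6423 ± 349 CPM (log2 fold change -0.51, edgeR adjusted p = 0.0112). INHBA, a subunit of the growth factor activin, was at 51.2 ± 2.35 against 90.5 ± 7.67 CPM (-0.82, edgeR adjusted p = 0.00888) and COL4A1 at 607 ± 31.2 against 796 ± 6.16 CPM (-0.39, edgeR adjusted p = 0.00346). PDK4 was at 4.26 ± 1.42 against 1.87 ± 0.0712 CPM (1.18, edgeR adjusted p = 0.0137) and CPT1A at 47.5 ± 11.6 against 30.2 ± 3.50 CPM (0.65, edgeR adjusted p = 0.0259). SLC7A11 and CHAC1 again rose, 2.29-fold and 2.37-fold (edgeR adjusted p = 0.00346 and 0.00134). CDH1 was at 10.3 ± 0.992 against 11.1 ± 0.834 CPM (edgeR adjusted p = 0.662). COL1A1 was at 3472 ± 730.0 against 4752 ± 782 CPM (-0.45, edgeR adjusted p = 0.0949) and SCD at 923 ± 50.9 against 1034 ± 14.7 CPM (edgeR adjusted p = 0.448), so that none of these 3 passed. COL1A1 did pass with a term for number 3 (-0.46, edgeR adjusted p = 0.00645) and from the libraries numbered 1 and 2 (4e-08), and SCD from the libraries numbered 1 and 2 but not with the term (0.323).

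In this comparison 486 genes passed, 192 higher and 294 lower, 51 of them changed at least 2-fold (17 higher, 34 lower), and the groups did not overlap for 23.6% of genes, where chance gives 10%. The count was 960 with only the 2 groups compared, 1683 with a term for number 3, 1853 from the libraries numbered 1 and 2, 1045 by DESeq2 and 1209 without Vehicle replicate 3. It was 55 and 64 without TGFβ + Aramchol replicates 1 and 2, 108, 97 and 128 without TGFβ replicates 1, 2 and 3, and 317 and 291 without Aramchol replicates 1 and 2. Of the 44 called genes named by rule, FN1, COL4A1, CHAC1, SLC7A11, CEBPG, H4C8 and IFIT2 kept their calls without each library in turn. The other 37 missed the threshold without 1 or more libraries, mostly of the groups compared, with a highest adjusted p between 0.053 (TCF7, without TGFβ + Aramchol replicate 1) and 0.193 (IRF7, without TGFβ replicate 3). For TGFBI it was 0.0644 and for INHBA 0.0583 (both without TGFβ + Aramchol replicate 1), for PDK4 0.0756 (without the same library) and for CPT1A 0.143 (without TGFβ + Aramchol replicate 2).

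Of 52 matrix genes 8 fell and 0 rose (21 and 0 adjusted over the list alone; camera adjusted p = 6.43e-17), and of 24 mesenchymal genes 8 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 1.6e-10). COL4A2 fell by 0.27, the myosin light chain gene MYL9 by 0.71, the cadherin gene CDH11 by 0.75 and SNAI1 by 0.39 on the log2 scale. Of 34 TGFβ targets 3 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 1.76e-07). Of 15 fibroblast markers 3 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 2.76e-07). PDGFRB fell by 0.45 and TAGLN by 0.69 on the log2 scale, the latter with a DESeq2 adjusted p of 0.0563. Notch and Wnt targets fell in 4 of 22 cases and rose in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0013), among them TCF7 and NOTCH3. With an estimated correlation, the adjusted p was 0.125 for matrix, 0.0679 for mesenchymal, 0.244 for target, 0.180 for fibroblast and 0.247 for Notch and Wnt genes (camera in limma). By fry, which asks whether a list's genes move one way on balance, the adjusted p was 0.0178 for matrix, 0.00533 for mesenchymal and 0.0450 for target genes. Senescence genes (2 of 21 lower, 3 adjusted over the list alone; camera adjusted p = 0.000259), glycolysis genes (1 of 32 lower, 2 adjusted over the list alone; 0.000525) and YAP and TAZ targets (1 of 23 lower, 1 adjusted over the list alone; 0.0211) passed downward by camera, with an adjusted p of 0.325, 0.444 and 0.722 with an estimated correlation.

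In the other direction, 6 of 43 PPARα and fatty acid oxidation genes rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.412 with an estimated correlation), including the lipid oxidation gene ECH1 by 0.37 on the log2 scale. Cell cycle genes rose in 3 of 46 cases and fell in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 6.55e-09, and adjusted p = 0.0679 with an estimated correlation). Of the 46, 41 had a positive log2 fold change, with a median of 0.11. E2F2 rose by 0.41 and CENPA, the histone variant of centromeres, by 0.33. Replication-dependent histone genes rose in 3 of 17 cases (6 adjusted over the list alone; camera adjusted p = 2.25e-05, and adjusted p = 0.0679 with an estimated correlation), with H4C8 uncertain as a member of a multigene family. Of 40 ER stress and integrated stress response genes 8 rose and 8 fell (13 and 11 adjusted over the list alone; camera adjusted p = 0.414). Those that rose were ATF4, CHAC1, CEBPG, SLC7A11, ASNS, PSAT1, TRIB3 and SLC3A2, genes of ATF4 signalling and amino acid supply. Those that fell were DNAJC3, HSP90B1, PDIA4, CALR, MANF, CRELD2, PDIA6 and HSPA5, genes of protein folding in the ER. Members outside the naming rule are given here because the list went both ways, which was chosen after their values were seen. Interferon genes passed upward by camera (1 of 35 higher and 2 lower, 10 and 4 adjusted over the list alone; camera adjusted p = 0.00273, and adjusted p = 0.770 with an estimated correlation). IFIT2 was 2.22-fold lower and OASL fell by 0.78, while IRF7 rose by 0.65 on the log2 scale. Among 27 epithelial genes 0 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.774), with a median of 0.05 and a mean of 0.08 while the camera direction was downward. Mitochondrially encoded genes passed downward (1 of 13 lower, 3 adjusted over the list alone; camera adjusted p = 0.00646, and adjusted p = 0.687 with an estimated correlation), with MT-CO1 falling by 0.29. Medians and means differed in sign for NRF2 targets (-0.03 and 0.05; camera adjusted p = 0.881), bile acid genes (-0.06 and 0.10; 0.691), hepatocyte markers (-0.01 and 0.07; 0.416) and endothelial markers (-0.13 and 0.03; 0.304), none of which passed.

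**Figure D3:**
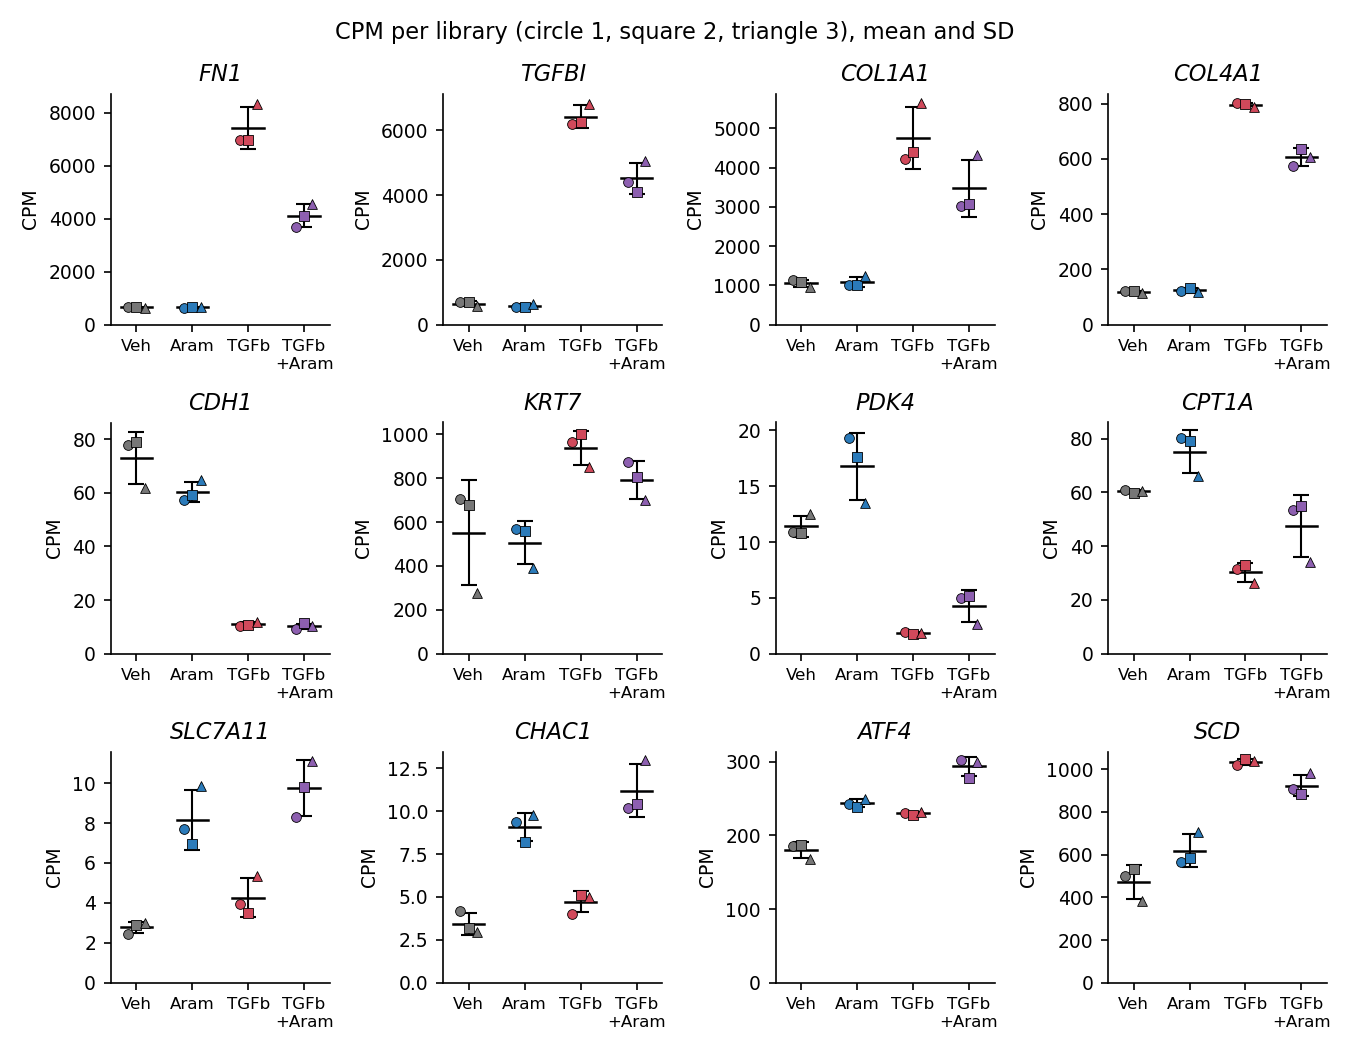
CPM of 12 genes in each of the 12 libraries, by group, with 1 point per library and the group mean and SD. FN1 lies at 659 ± 29.4 in vehicle, 7418 ± 798 with TGFβ, 659 ± 16.5 with Aramchol and 4110.0 ± 434 with both, and COL1A1 at 4752 ± 782 with TGFβ and 3472 ± 730.0 with both.

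The largest changes by rule in this comparison were in genes of several kinds. Besides CHAC1 and SLC7A11, the largest rises were in EREG, a ligand of the EGF receptor, by 0.81, SMOC1 by 0.78, PSAT1, an enzyme of serine synthesis, by 0.75 and PTX3 by 0.70 on the log2 scale. The largest falls were in CYP24A1, the enzyme that inactivates vitamin D, at 30.4 ± 2.13 against 94.2 ± 15.3 CPM (edgeR adjusted p = 0.0220, 0.0523 by DESeq2), and in LRRC15, IFIT2, PSG5, STRA6 and HEYL, which fell by 1.28, 1.15, 1.14, 1.12 and 1.11 on the log2 scale. PSG5 has near-identical family members and is uncertain. No gene of the fatty acid synthesis list passed (0 of 28 by edgeR, 0 adjusted over the list alone; camera adjusted p = 0.759), and 1 of 27 cholesterol synthesis genes rose (1 adjusted over the list alone; camera adjusted p = 0.285).

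Whether Aramchol opposed the TGFβ response was counted over the 7978 genes that TGFβ changed. Of these, 339 moved back toward vehicle with Aramchol (213 that TGFβ had raised and 126 that it had lowered) and 44 moved further (19 and 25). The 339 make up 4.25%, a share that depends on the threshold and the fit: with a term for number 3, 1102 of 9160 genes moved back. Independent lists of the sizes in the main fit would share 55.5 and 34.8 genes moving back, and 36.2 and 53.3 moving further. Both contrasts use the same TGFβ libraries, with opposite signs. Simulated data with the TGFβ effect and no Aramchol effect gave 0.05 genes moving back on average over 20 simulations (at most 1). In these data only 0.3 genes on average (at most 2) were called in TGFβ + Aramchol against TGFβ. The simulated count was therefore bound to be small with or without sharing, and does not test it. Across the 14387 genes at a mean of at least 1 CPM, the covariance of the 2 contrasts' log2 fold changes was -0.0653, against -0.00821 in that simulation. Over the same genes their correlation was -0.424, against -0.0877 in that simulation and -0.504 in simulated data with no effect at all. The share of opposite signs over all TGFβ-called genes, whatever their CPM, was 72.4%, against 58.3% in the simulation. The simulation without an Aramchol effect shares the TGFβ libraries in the same way. Its covariance and its share of opposite signs argue against sharing, at the simulated spread between libraries, as the source of the excess. A deviation common to all 3 TGFβ libraries was not simulated and may add to it. They cannot be split into parts of at least 2 to test this. The count moving back was 1102 with a term for number 3, 1179 from the libraries numbered 1 and 2, 676 by DESeq2 and 741 without Vehicle replicate 3. It was 35 and 44 without TGFβ + Aramchol replicates 1 and 2, 76, 70 and 81 without TGFβ replicates 1, 2 and 3, and 224 and 207 without Aramchol replicates 1 and 2. In the same fits and order, the count moving further was 161, 201, 93 and 125, then 9 and 9, then 10, 8 and 18, then 35 and 31.

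A measure with no shared library set the TGFβ response with Aramchol (TGFβ + Aramchol against Aramchol) against that without (TGFβ against vehicle). The orthogonal slope over 9993 genes was 0.899, a TGFβ response about 10% smaller with Aramchol. With the jackknife taken within groups, its SE was 0.0368, and 2 SE on either side ran from 0.826 to 0.973, which excluded 1. This SE was added after the results were seen and rests on 3 libraries per group. With the 12 libraries taken as 1 sample, which adds the differences between groups, the SE was 0.0871 and the range of 0.725 to 1.07 included 1. It was 0.911 for genes that TGFβ raised, 0.874 for genes that it lowered and 0.906 for genes changed at least 2-fold. Leaving out 1 library moved it between 0.864 and 0.939. In simulated data without an Aramchol effect the slope was 0.999 (0.980 to 1.02). Each gene was drawn on its own there, without deviations that many genes of a library share. That range is therefore too narrow to serve as the range of chance for the slope. Genes are not independent replicates, so no p-value is given.

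**Figure D4:**
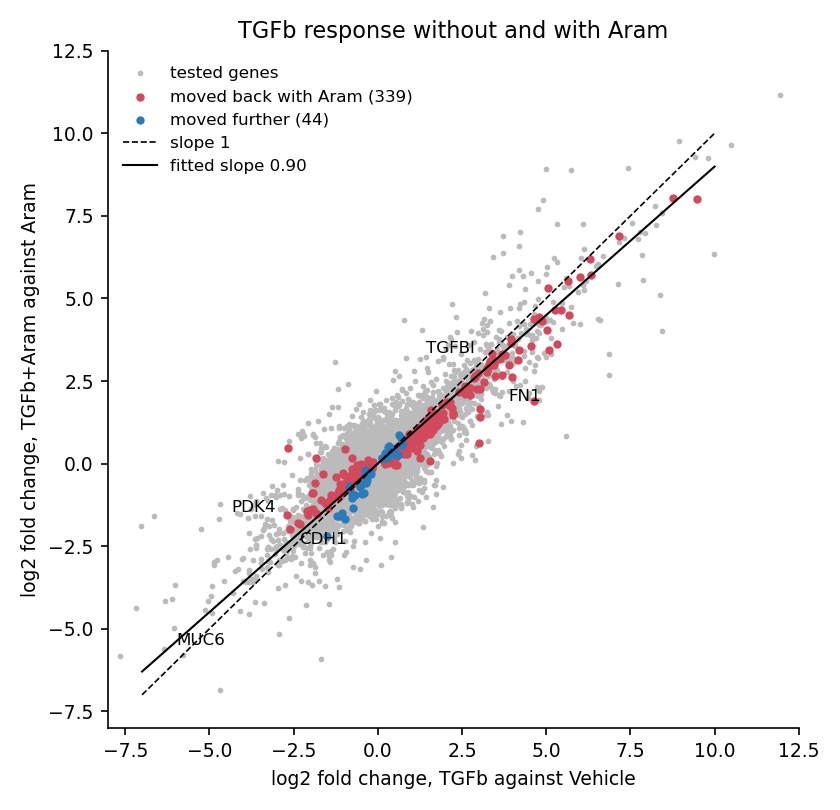
Log2 fold change of TGFβ + Aramchol against Aramchol (vertical axis) on that of TGFβ against vehicle (horizontal axis), 1 point per gene. Red points are the 339 genes moved back and blue points the 44 moved further by Aramchol, the dashed line has a slope of 1 and the solid line is the fitted slope of 0.899.

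The responses to Aramchol in stimulated and unstimulated cells come from separate libraries. Of the 77 genes called in unstimulated cells 43 were also called in stimulated cells, 30 higher in both and 12 lower in both, where independent lists would share 0.454 and 0.354. Both contrasts come from 1 fit with 1 estimate of the spread per gene. A gene with a low estimate is favoured in both lists, so the numbers for independent lists may be too low. The overlap was not counted in other settings. It cannot be as large without Aramchol replicate 1 or 2, where 18 and 16 genes were called in unstimulated cells, 1 of them lower in each fit. JAG1, a Notch ligand, was the only gene called in opposite directions (0.29 in unstimulated and -0.18 in stimulated cells). Of the 77 genes 72 (93.5%) had the same sign in stimulated cells, and of the 486 genes 439 (90.3%) had it in unstimulated cells. The correlation of the 2 log2 fold changes across genes was 0.673 over the 520 genes called in either and 0.206 over all tested genes. Genes shared by both included SLC7A11 (2.94-fold and 2.29-fold), CHAC1 (2.65-fold and 2.37-fold), TRIB3 (log2 fold changes 0.55 and 0.45) and CEBPG, a partner of ATF4 (0.47 and 0.47).

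The interaction asked whether the effect of Aramchol differed between stimulated and unstimulated cells. Its 3 called genes were all more lowered, or less raised, by Aramchol in stimulated cells (edgeR), against 1137 genes at an unadjusted p under 0.05 and 30 called by DESeq2. For FN1 the difference was -0.85 (SE 0.11, edgeR adjusted p = 0.0205), from 0.00 in unstimulated to -0.85 in stimulated cells. JAG1 (ENSG00000101384, chromosome 20, 10637684 to 10673999, minus strand) was at 64.9 ± 0.723 CPM in vehicle, 79.3 ± 2.55 with Aramchol, 186 ± 1.39 with TGFβ and 164 ± 3.17 with both (difference -0.47, SE 0.06, edgeR adjusted p = 0.0205). SEC24D (ENSG00000150961, chromosome 4, 118722823 to 118838683, minus strand), a coat protein of vesicles that leave the ER, was at 58.5 ± 0.912, 83.6 ± 1.75, 112 ± 5.85 and 113 ± 3.87 CPM in the same order (difference -0.51, SE 0.07, edgeR adjusted p = 0.0233). The count was 0 without Vehicle replicate 1 or 2, TGFβ replicate 2 or 3, Aramchol replicate 1 or 2, or TGFβ + Aramchol replicate 1 or 2, 2 without TGFβ replicate 1 and 7 without Vehicle replicate 3. It was 31 with a term for number 3 and 191 from the libraries numbered 1 and 2. The difference was -0.44 for COL4A1 (edgeR adjusted p = 0.175) and 0.62 for PDK4 (0.943), so that an Aramchol effect called in stimulated cells alone was not shown to differ for these 2 genes. With a term for number 3 it passed for COL4A1 (0.0120) and not for PDK4 (0.448). For SCD, called in neither state, it was -0.56 (edgeR adjusted p = 0.683, and 0.129 with that term). By camera 15 lists passed in the interaction, of which 0 passed with an estimated correlation. Among them were the matrix list, lower in stimulated cells (1 of 52 called, 7 adjusted over the list alone; camera adjusted p = 4.72e-19, and adjusted p = 0.188 with an estimated correlation) and the cholesterol synthesis list, also lower (0 of 27 called by edgeR, 1 adjusted over the list alone; camera adjusted p = 1.27e-12, and adjusted p = 0.308 with an estimated correlation).

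TGFβ + Aramchol against Aramchol gave the cytokine response in the presence of the compound. FN1 went from 659 ± 16.5 to 4110.0 ± 434 CPM and CDH1 from 60.4 ± 3.81 to 10.3 ± 0.992 CPM. Of 27 cholesterol synthesis genes 0 rose and 12 fell (14 adjusted over the list alone; camera adjusted p = 0.000161, and adjusted p = 0.526 with an estimated correlation). Of 34 TGFβ targets 32 rose and 1 fell (32 and 1 adjusted over the list alone; camera adjusted p = 9.56e-31), of 52 matrix genes 40 rose and 3 fell (40 and 3; 8.64e-22) and of 24 mesenchymal genes 18 rose and 2 fell (19 and 2; 2.26e-15), with an adjusted p of 0.0319, 0.0868 and 0.0319 with an estimated correlation. With a term for number 3 as well, the targets (0.0580) and the mesenchymal genes (0.0885) missed the threshold. In all 6514 genes passed (edgeR), 3450 higher and 3064 lower (3112 and 3493 with upper quartile scaling), 1896 at least 2-fold, and the groups did not overlap for 44.6% of genes against 10% by chance. CCL2 passed here (0.86, edgeR adjusted p = 0.0384) but not without Aramchol replicate 1 or 2, TGFβ replicate 2 or TGFβ + Aramchol replicate 1 or 3 (up to 0.158).

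TGFβ + Aramchol against vehicle gave the net state of cells that received both. FN1 remained 2.64 above vehicle on the log2 scale, and PMEPA1, a feedback inhibitor of TGFβ signalling, was 4.15 above vehicle on the log2 scale. Of 34 TGFβ targets 29 rose and 1 fell (30 and 1 adjusted over the list alone; camera adjusted p = 1.6e-25), of 52 matrix genes 40 rose and 4 fell (41 and 4; 1.16e-19) and of 24 mesenchymal genes 17 rose and 2 fell (18 and 2; 8.22e-14), with an adjusted p of 0.0497, 0.122 and 0.0497 with an estimated correlation. Both values of 0.0497 became 0.0861 with a term for number 3. Of 40 ER stress and integrated stress response genes 33 rose and 0 fell (33 and 0 adjusted over the list alone; camera adjusted p = 8.22e-14, and adjusted p = 0.124 with an estimated correlation). SCD was 1.96-fold above vehicle, and ODAPH went from 0.573 ± 0.195 to 47.6 ± 3.97 CPM. In all 7593 genes passed (edgeR), 3928 higher and 3665 lower (3252 and 4410 with upper quartile scaling), 2156 at least 2-fold, and the groups did not overlap for 44.0% of genes against 10% by chance.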

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

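The counts of regroupings and the tests of scaling and of the libraries numbered 3 were chosen only after the results were seen, while the test of gene length and GC content was written before.

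The effect of Aramchol differed between stimulated and unstimulated cells, by the interaction test, for FN1 (-0.85), SEC24D (-0.51) and JAG1 (-0.47). With RLE or upper quartile scaling the largest adjusted p of the 3 genes was 0.02485, with a term for number 3 and without those libraries 0.001652, and after removing the trend with gene length and GC content the smallest difference was 7.017 standard errors, which argues against each of these as the whole cause. The calls were not firm all the same: over leave-one-out fits the adjusted p ran from 0.00971 to 0.144 for FN1, 0.015 to 0.145 for JAG1 and 0.0242 to 0.152 for SEC24D, highest without Aramchol replicate 1 for each. Of 100 regroupings (of 200 possible) 6 called at least 3 genes, the highest other 697, but all 6 kept the TGFβ libraries apart from the TGFβ + Aramchol libraries and so hold the real effect of Aramchol, which leaves chance in the grouping undecided. A biological effect of Aramchol on the TGFβ response of these 3 genes may remain, as a hypothesis found and tested on the same data.

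The same interaction test passed by camera for 15 lists. Lower with Aramchol in stimulated than in unstimulated cells were TGFβ targets (adjusted p = 0.000195), matrix genes (4.72e-19), mesenchymal genes (2.8e-08), senescence genes (0.000525), SREBP1 and fatty acid synthesis genes (0.000676), cholesterol synthesis genes (1.27e-12, 0 of 27 positive), ER stress and integrated stress response genes (1.14e-07), glycolysis genes (0.00642), YAP and TAZ targets (0.0314), Notch and Wnt targets (0.0124), fibroblast markers (0.0013) and keratinocyte genes (0.00484). Higher were cell cycle genes (6.91e-05), ribosomal protein genes (4.51e-05) and histone genes (0.0057). With an estimated correlation, the adjusted p of these 15 lists ran from 0.188 to 0.637, and by fry from 0.202 to 0.761, so that none passed.

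For each of the 5 comparisons of groups (7978 genes for TGFβ, 77 for Aramchol, 486, 6514 and 7593 for TGFβ + Aramchol against TGFβ, Aramchol and vehicle) and for the 339 genes moved back, the real split was the 1 of 10 that gave as many genes and the highest other gave 0. The 10 splits of 3 against 3 are too few for a share under 0.05. For the slope of 0.899, 6 of 100 regroupings lay as far from 1, the furthest at 1.148, and 5 of these 6 kept the TGFβ libraries apart from the TGFβ + Aramchol libraries, so that this count does not decide about chance either.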

How the results depend on the processing

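The term for number 3, the libraries numbered 1 and 2 alone, the robust fit and the jackknife within groups were chosen only after the results were seen. No called gene changed direction in any setting, and of the lists that passed 1 did. The secretory list, which did not pass, was lower by camera and higher by fry in TGFβ against vehicle and in TGFβ + Aramchol against Aramchol. TGFβ against vehicle gave 6833 to 9160 genes over all settings, TGFβ + Aramchol against Aramchol 5262 to 7775, against vehicle 6276 to 8768, and the slope 0.864 to 0.939. The other 4 counts moved by more than 1.5 times, and the cause was not tested.

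For Aramchol against vehicle (77 genes), TGFβ + Aramchol against TGFβ (486), the interaction (3) and genes moved back (339), the counts were 531, 1278, 151 and 881 with no filter, 396, 1045, 30 and 676 by DESeq2, 538, 1683, 31 and 1102 with a term for number 3, and 1544, 1853, 191 and 1179 with the libraries numbered 1 and 2. With only the 2 groups compared the first 2 were 5 and 960. Leaving out 1 library gave 16 (without Aramchol replicate 2) to 611 (without Vehicle replicate 3), 55 (without TGFβ + Aramchol replicate 1) to 1209 (without Vehicle replicate 3), 0 (edgeR, without Vehicle replicate 1 among others) to 7 (without Vehicle replicate 3) and 35 (without TGFβ + Aramchol replicate 1) to 741 (without Vehicle replicate 3). YAP and TAZ targets in the interaction went from a camera adjusted p of 0.000664 (without Vehicle replicate 1) to 0.340 with the direction reversed (without Vehicle replicate 3), and missed the threshold without TGFβ replicate 2, Aramchol replicate 1 or 2, or TGFβ + Aramchol replicate 3 as well.

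With replicate number as a block the 4 counts were 464, 1519, 23 and 1000. Numbers were not taken as paired: 7 of 18 pairs of libraries with the same number correlated above 0.1 over all tested genes, and 17 of 18 over genes above 10 CPM (median 0.38, against -0.31 for other pairs). The value of -0.31 pools pairs that hold a library numbered 3 with pairs that hold none. Above 10 CPM, pairs of a library numbered 1 with one numbered 2 ran from -0.149 to 0.438. Same-number pairs ran from -0.087 to 0.520 for numbers 1 and 2, and from 0.303 to 0.703 for number 3. The contrast of the medians thus shows number 3 apart, more than a pairing within numbers 1 and 2. Of 12 libraries 9 correlated best with their own number. With an estimated correlation, the TGFβ targets and the mesenchymal genes missed the threshold under the block (0.0916 for both in TGFβ against vehicle, 0.0819 and 0.0965 in TGFβ + Aramchol against Aramchol, 0.0882 and 0.138 against vehicle).

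Small effects were missed more often: in simulated data 80% of genes changed 1.5-fold were called in TGFβ + Aramchol against TGFβ and 70% in the interaction, and at the smallest fold simulated 36% and 12%. Depth was not varied, so its part in this was not tested.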

Other observations

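The test of depth for the libraries numbered 3, the fractions without removal of a shift, and the test of expression, length and GC content for the amino acid and ER folding genes, were chosen only after the results were seen.

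The libraries numbered 3 differed from those numbered 1 and 2 across all 4 groups in 2725 genes, 1141 higher and 1584 lower, 120 of them at least 2-fold. Lower were the cytokine gene IL6 (-0.90), CSF3 (-1.15), CCL5 (-0.95) and the Wnt inhibitor gene DKK1 (-1.16), and higher were EGR1 (0.59), NCAM1 (0.62) and the collagen gene COL6A3 (0.57), all chosen after their values were seen. Depth would put number 3 at one end of every group, but it had the highest total in 2 groups and the lowest in 1, and 97.18% of the genes kept their direction and at least 0.5 of the difference after removing the trend with gene length and GC content. RNA of Aramchol cells in Vehicle replicate 3 would move all 486 genes called in TGFβ + Aramchol against TGFβ by one fraction: with the shift of number 3 in the TGFβ groups removed, the fraction was 0.8205 over all of them, but 0.322 (SE 0.103) for the rising and 1.08 (SE 0.139) for the falling genes, and without that removal 0.571, 0.0941 (SE 0.0841) and 0.820 (SE 0.115). These SE are over genes, which are not independent replicates, and Vehicle replicate 3 is 1 library. The gap between rising and falling genes thus has no measured spread between libraries, and such RNA is not excluded. A batch or a day shared by these libraries may remain as well. The labels give none, but the running number in the library names places the libraries numbered 3 together, after the others.

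In stimulated cells with Aramchol, the 8 genes of the stress response list that rose were of ATF4 signalling and amino acid supply, and the 8 that fell were of ER protein folding. They were 8 of 25 genes of the first kind (median 0.27) and 8 of 15 of the second (median -0.30), kinds that were set after the values were seen. HSP90B1, an ER chaperone, was at 1030.0 ± 53.9 against 1402 ± 27.2 CPM, and its level in unstimulated cells was 742 ± 48.1 with and 795 ± 101 without Aramchol (interaction -0.35, adjusted p = 0.827). The values on which the kinds were set include those of the libraries numbered 1 and 2. In these the difference of the medians was 95.18% as large, so that it did not rest on the libraries numbered 3 alone. It lay at percentile 100 of 10000 pairs of random lists matched for expression, length and GC content, but the choice of genes after their values were seen fixes such an outcome, so these 3 stay open.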
